A study of Mus musculus with 6 samples.

How the data were processed

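RNA sequencing of mouse embryonic stem cells was analysed in 6 libraries. They cover wild-type cells (WT), cells homozygous for the missense change C54Y in the DNA-binding zinc finger of THAP1 (C54Y), and cells lacking THAP1 after deletion of exon 2 of Thap1 (KO), with 2 libraries of each, numbered replicate 1 and replicate 2. Per the labels, the cells came from C57Bl/6 blastocysts and grew on irradiated fibroblast feeders with serum and LIF at 1000 units per ml, and libraries were made with a TruSeq kit. The submitters' processing notes name CASAVA, Trimmomatic, TopHat2 2.1.0, HTSeq, DESeq2 and the mouse build mm9; strand setting, gene annotation and filters were not stated.

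The deposited table gives 1 signal value per gene and library, a normalized count: reads per gene divided by 1 size factor per library. Every value was a whole multiple of its column's smallest step within a tolerance of 1e-06, so whole reads were recovered, and the steps equalled DESeq2 size factors recomputed from those reads. Recovered reads came to 41779273 (WT replicate 1), 46772996 (C54Y replicate 1), 40640369 (KO replicate 1), 32356572 (WT replicate 2), 31774656 (C54Y replicate 2) and 35285464 (KO replicate 2). The table held 19713 genes, and 15287 with a normalized count of at least 10 in at least 2 libraries were tested. Gene symbols were matched to RefSeq names of GRCm38.p6 for chromosomes (15220 genes, 99.56%) and to GENCODE M21 for length and GC content (15168 genes, 99.22%). Shld1 appears in the table under its older symbol 1110034G24Rik. List members without a matching symbol in the table were Tcstv1, Tcstv3, Gm4340, Rhox5, Shld3, Hmgcs1 and Thap8.

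Differences were tested with limma 3.58.1 (robust trend) in R 4.3.3 on log2 of the normalized count plus 2, over all 6 libraries, with p-values adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The plan had named edgeR with TMM factors, on the assumption that the table held raw counts. Since the values were already normalized, limma was used for the main result and edgeR 4.0.16 on the recovered reads became an alternative. The planned model held the group alone. Replicate number as a block had been set out in advance as a second choice. Deviations of the libraries from their group means correlated at 0.907 (WT and C54Y), 0.869 (WT and KO) and 0.895 (C54Y and KO) across genes, so the replicate numbers pair the samples. This pairing was settled before any calls were compared. The labels do not say what the replicate number marks, nor whether the libraries of a group came from separate cultures or clones. The p-values of single genes therefore measure only the spread between these samples. Because the block changed the calls, both fits are given, and named genes and gene lists are described from the blocked fit, which has 2 residual degrees of freedom against 3 without the block. Log2 fold changes do not differ between the fits.

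Recovery was tested on simulated data with the same replicate structure. Without the block, limma recovered 0 of 50 genes at each fold. With the block it recovered 4% at 1.5-fold, 50% at 2-fold and 92% at 4-fold, 5 of its 124 calls were on unchanged genes, and an unchanged comparison gave 0 calls by limma and 2 by edgeR. Unchanged genes shared the same replicate difference in all simulated genotypes, and genes varied independently. The share of false calls therefore need not hold for the data.

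Gene lists (33) were written before the data were examined, as were the main comparisons, the alternative settings and the rule for naming genes. Lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists of a comparison. At the preset correlation the members are set against all other genes, so these p-values do not measure the spread between samples. The same holds for the later test of chromosomes. On simulated data the preset test called the shifted list and 0 others, while the estimated correlation (adjusted p = 0.225) and fry (adjusted p = 0.151) did not call it. Simulated genes varied independently, so this cannot show how the preset test behaves where members of a list vary together. Because the estimated correlation and fry missed a list that was shifted, a list they did not call is not shown to be unchanged. Correlations estimated in the blocked fit were 0.034 for endoderm, 0.204 for naive, 0.597 for two-cell-like and 0.851 for germline genes. Counts "adjusted over the list alone" use the blocked p-values of the list's members. The naming rule covered Thap1, Rrm1, Shld1, Psmb5, Tor1a, Yy1, Pou5f1, Sox2 and Nanog in every comparison. It added the 6 genes with the largest changes in each direction that passed 0.05, had a mean of at least 3 CPM (reads scaled to a common library total) and kept the libraries of both groups apart. It also took up to 4 members with the smallest p for each described list, the 5 genes changed most in each direction in both mutants, and sex-chromosome transcripts in the closing section. Because the unblocked fit called nothing, the rule was applied to the blocked fit.

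Alternatives were other scaling factors (upper quartile, and TMM for the lists), other filters, DESeq2 1.42.0, limma-voom, a minimum fold of 1.5, fits on the 4 libraries compared, and fits with each library left out. Besides edgeR with TMM factors, the test first planned, those added after the data were seen were limma with TMM factors, pseudocounts of 0.5 and 8 for single genes, a correction for GC content and gene length within each replicate number, and the block combined with each alternative. With 1 library left out, the remaining library of that group was assumed to vary like the other groups. It then adds nothing to the residual spread. Blocked fits with a library left out, or on the 4 libraries compared, have fewer residual degrees of freedom than the full fit. Their counts of calls therefore do not measure robustness. The overlap with neither mutant changed was taken from 100 draws in which 2 unchanged groups were compared with the same drawn WT libraries. Draws with KO changed and C54Y unchanged were not made. Exon-level reads, the C54Y base change and splicing were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.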

Results

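Gene expression was measured by RNA sequencing in mouse embryonic stem cells of 3 genotypes, WT, C54Y and KO, with 2 libraries each. THAP1 is a zinc finger transcription factor whose mutations cause the movement disorder DYT6 dystonia, and C54Y changes a residue of its DNA-binding domain. Library depth ranged from 31774656 to 46772996 reads, and 17061 to 18481 genes had reads. The first principal component carried 73.8% of the variance and parted replicate 1 from replicate 2. The second carried 17.6% and ordered the libraries WT, C54Y, KO within each replicate. Between the replicates of a genotype, 37.2% (WT), 37.6% (C54Y) and 42.8% (KO) of tested genes differed over 2-fold. Within replicate 1, WT and KO differed over 2-fold in 18.5% of genes, and within replicate 2 in 15.5%. The pre-ribosomal transcript Rn45s made up 0.472% to 0.600% of reads in replicate 1 and 1.49% to 2.05% in replicate 2, so the replicate numbers also marked a difference in library composition. The median residual SD per gene was 0.593 on the log2 scale without the replicate block and 0.201 with it.

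Thap1 itself, on chromosome 8, had more reads in both mutants than in WT. Normalized counts averaged 567 ± 190 in WT (SD, n = 2), 1831 ± 204 in KO and 2393 ± 198 in C54Y. The rise was 1.72 ± 0.22 in KO (log2 fold change ± SE, adjusted p = 0.0018) and 2.11 ± 0.22 in C54Y (adjusted p = 0.00301), by limma with the replicate block and Benjamini-Hochberg adjustment. A difference between the mutants was not called (KO against C54Y -0.39, adjusted p = 0.431). A count over the whole gene tests neither the deletion nor the missense change. Shld1, a subunit of the shieldin complex that guides DNA double-strand break repair, fell in KO (-2.63 ± 0.30, adjusted p = 0.00121) and in C54Y (-3.37 ± 0.30, adjusted p = 0.00176). Psmb5, a catalytic subunit of the proteasome, fell in C54Y (-0.83, adjusted p = 0.0216) and in KO (-0.46, adjusted p = 0.0473). The C54Y call for Psmb5 was lost without C54Y replicate 1 (adjusted p = 0.162), C54Y replicate 2 (0.326) or WT replicate 2 (0.0628). The KO call was lost without WT replicate 1 (0.287), WT replicate 2 (0.211), C54Y replicate 1 (0.127) or C54Y replicate 2 (0.16). No change was called for Rrm1, which encodes a ribonucleotide reductase subunit (0.31 in KO, adjusted p = 0.146; 0.23 in C54Y, adjusted p = 0.543). Tor1a, the gene of another inherited dystonia, stood at -0.04 and -0.12 (adjusted p = 0.911 and 0.861), and Yy1 at -0.13 and -0.09 (adjusted p = 0.714 and 0.923).

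**Figure D1:**
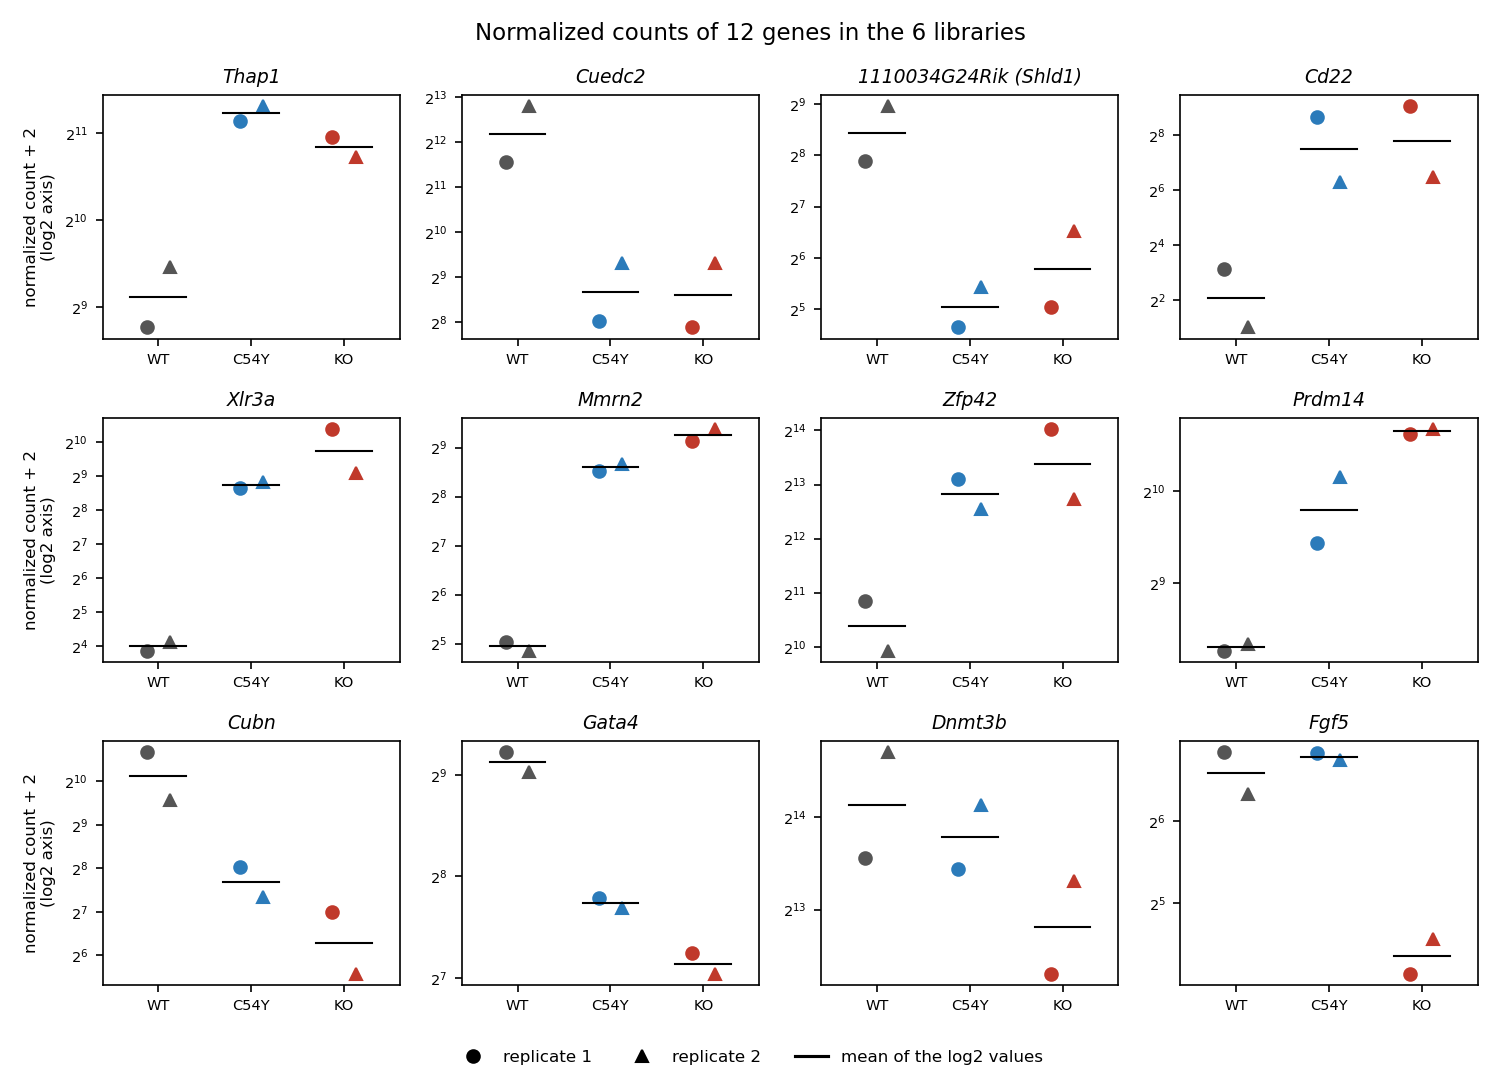
Normalized counts plus 2 (log2 axis) of 12 genes in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2 and bars at the mean of the log2 values. Thap1 lies higher and Cuedc2 lower in all 4 mutant libraries than in the WT libraries, while Fgf5 is low in KO alone.

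The comparison of KO with WT asked which transcripts differ in the cells lacking THAP1. Cuedc2, which encodes a ubiquitin-binding CUE domain protein, went from 5049 ± 2897 normalized counts in WT to 437 ± 286 in KO (SD, n = 2). Its fall of -3.57 ± 0.17 had the lowest adjusted p of all genes (8.92e-05). The endocytic receptor Cubn (-3.84 ± 0.25, adjusted p = 0.000195), the proteoglycan Srgn (-3.61 ± 0.30), the guidance receptor gene Sema6a (-3.50 ± 0.30), the neuroendocrine transcription factor Insm1 (-3.47 ± 0.36) and the metal transporter Slc39a8 (-3.37 ± 0.56) also fell. Genes that rose most were Cd22, a lectin best known from B cells (5.72 ± 0.32, adjusted p = 0.000125), the X-linked homeobox gene Rhox1 (4.53 ± 0.31) and the X-linked Xlr genes Xlr3a (5.75 ± 0.37), Xlr5a (5.80) and Xlr3b (4.86), with Xlr5b going from 1.76 to 256 normalized counts. WT counts of Cd22, Xlr5a, Xlr5b and Xlr3b averaged 6.37 or fewer, which leaves their folds imprecise, and Xlr genes belong to multicopy families that share reads.

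With the block, limma called 2494 genes between KO and WT after Benjamini-Hochberg adjustment, 1361 up and 1133 down. All 2494 had the same sign in both replicates, against 65.6% of all tested genes, but the blocked fit selects for such agreement. In 1844 of them the libraries of the 2 groups did not overlap. The balance of directions depended on scaling: 54.6% of calls were up with the deposited size factors, while edgeR with TMM factors called 1085 up and 1331 down. Without the block, limma called 0 genes, with 1049 at an unadjusted p under 0.05. Other unblocked fits called 0 (edgeR), 0 (limma-voom) and 184 (DESeq2). With the block, the count rose without either KO library and fell without any WT or C54Y library. A KO library left alone adds nothing to the residual spread, so the rise is no sign of robust calls.

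Most genes of the naive pluripotent state rose in KO. Zfp42 (Rex1), a marker of naive cells, rose by 2.98 ± 0.18 (adjusted p = 0.000187), and Tcl1, Prdm14, Esrrb and Nanog rose by 2.53, 2.34, 1.13 and 1.46. Of the core factors, Pou5f1 rose by 0.65 ± 0.10 (adjusted p = 0.00439), Dppa5a by 0.74 and Trim28 by 0.49, while Sox2 was not called (0.43, adjusted p = 0.0742). Some formative and primed genes went down, among them the de novo methyltransferase Dnmt3b (-1.32 ± 0.14, adjusted p = 0.000937), the growth factor Fgf5 (-2.24), Pou3f1 (-1.61) and Sfrp2 (-1.69). Some genes of 3 lineages were lower too. Of the endoderm genes Cubn, Dab2 (-2.79 ± 0.21, adjusted p = 0.000224), Gata4 (-1.98 ± 0.22) and Amn (-2.20) fell, of the mesoderm genes Wnt3 (-2.97) and Hand1 (-1.87), and of the neuroectoderm genes Neurod1 (-2.43) and Sox11 (-1.61), although the neuronal genes Tubb3 (0.84) and Ncam1 (1.26) rose. The mesoderm gene Gsc was called up, a call lost without WT replicate 2 or KO replicate 2.

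As lists, naive genes were called up (15 up and 0 down of 19 tested; adjusted over the list alone 17 up and 1 down; camera adjusted p = 2.98e-11). Endoderm genes were called down (0 up and 10 down of 18; adjusted over the list alone 0 and 11; adjusted p = 1.54e-07). Formative genes had 1 up and 6 down of 16 (adjusted over the list alone 3 and 9; adjusted p = 0.00351). Mesoderm genes had 1 up and 5 down of 15 (adjusted over the list alone 1 and 8; adjusted p = 0.00351), neuroectoderm genes 2 up and 4 down of 14 (adjusted over the list alone 2 and 5; adjusted p = 0.0178), and core factors 6 up and 0 down of 15 (adjusted over the list alone 7 and 1; adjusted p = 0.0178). None of these list calls held with an estimated correlation (adjusted p = 0.49 with an estimated correlation for each, and 0.507 for core factors). That test also missed the shifted list on simulated data, so it does not decide whether these lists changed. The core call was lost without KO replicate 1 (0.128) or WT replicate 1 (0.0875), and the mesoderm call without KO replicate 1 (0.0634). Fibroblast markers, which trace the feeder cells, were also called down (0 up and 1 down of 24, Mmp2 at -1.03; adjusted over the list alone 0 and 0; adjusted p = 0.00454, and adjusted p = 0.621 with an estimated correlation). Their median was -0.849 in replicate 1 and -0.0806 in replicate 2, and their call was lost without KO replicate 1 (0.627) or WT replicate 1 (0.209). The Mmp2 call was lost without WT replicate 1 (0.0768).

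**Figure D2:**
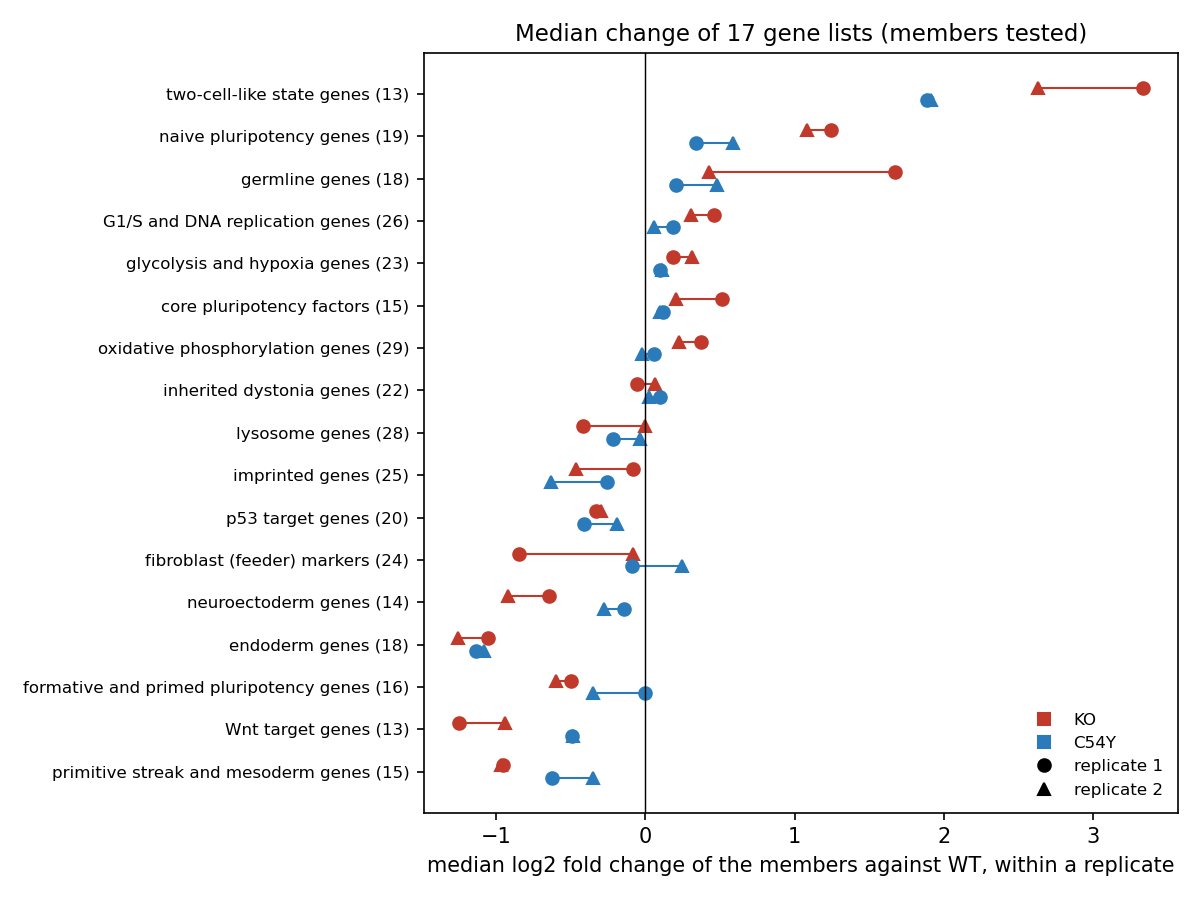
Median log2 fold change against WT of the members of 17 gene lists, within replicate 1 (circles) and replicate 2 (triangles), for KO (red) and C54Y (blue), with members tested in brackets. Naive and two-cell-like lists lie above 0 and the endoderm list below 0 in both mutants and both replicates, while the fibroblast markers of KO lie at -0.849 and -0.0806.

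Most tested genes of the two-cell-like state and some of the germ line also rose in KO. Dux, which drives the two-cell-like programme, went from a mean of 1.29 normalized counts in WT to 25.2 in KO (adjusted p = 0.00533). Tmem92 went from 4.88 to 100.1 and Usp17le from 2.30 to 34.1, so folds of these genes are imprecise. The meiotic gene Sycp1 (2.61), the testis tubulin Tuba3a (3.22 ± 0.23, adjusted p = 0.000203) and the transposon-silencing gene Tex19.1 (1.98) rose as well. The two-cell-like list had 11 up and 0 down of 13 (adjusted over the list alone 12 and 0; camera adjusted p = 1.54e-07, and adjusted p = 0.507 with an estimated correlation). Several of its members are near-identical copies that share reads. The germline list had 8 up and 1 down of 18 (adjusted over the list alone 10 and 1; adjusted p = 0.000633, and adjusted p = 0.621 with an estimated correlation). Among imprinted genes, Grb10 (-2.16 ± 0.17, adjusted p = 0.000251), Nnat (-2.27) and Peg10 (-1.05) fell and Peg12 (1.93) rose. The list had 3 up and 9 down of 25 (adjusted over the list alone 3 and 9; adjusted p = 0.0297, and adjusted p = 0.49 with an estimated correlation).

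Genes of metabolism, growth, signalling and disease were examined as well. The glycolytic enzyme genes Pfkp (1.42 ± 0.16, adjusted p = 0.00102), Pgk1 (0.85) and Ldha (0.61) rose, and their list had 7 up and 1 down of 23 (adjusted over the list alone 8 and 2; adjusted p = 0.00762). Pgk1 and the Ndufa1 gene named next are X-linked, and X-linked genes had a median of 0.62 in KO. Their rises cannot be told apart from that of the chromosome. Oxidative phosphorylation genes had 5 up and 0 down of 29 (adjusted over the list alone 5 and 0; adjusted p = 0.00454), with Ndufa1 at 0.81, and the call was lost without KO replicate 1 (0.129) or WT replicate 1 (0.151). Among G1/S genes the helicase subunit Mcm5 rose by 0.60, with 6 up and 1 down of 26 (adjusted over the list alone 15 and 1; adjusted p = 0.000255), a call lost without WT replicate 1 (0.0638). Wnt targets were called down (2 up and 5 down of 13; adjusted over the list alone 2 and 9; adjusted p = 0.0199), with the antagonist gene Dkk1 at -2.42 but another, Notum, at 2.15, and the call was lost without KO replicate 1 (0.173). p53 targets had 2 up and 4 down of 20 (adjusted over the list alone 2 and 7; adjusted p = 0.0351). That call was lost without WT replicate 1 (0.209), KO replicate 1 (0.0861), C54Y replicate 1 (0.0774) or C54Y replicate 2 (0.0687). With an estimated correlation none of these lists passed (adjusted p = 0.49 with an estimated correlation for glycolysis and Wnt targets, 0.507 for p53, 0.577 for G1/S and 0.614 for oxidative phosphorylation). Lysosome genes were not called (1 up and 4 down of 28; adjusted over the list alone 1 and 6; adjusted p = 0.0519, against 0.0435 with TMM factors), although the enzyme genes Gusb (-2.11 ± 0.19, adjusted p = 0.00047) and Ctsl (-0.77) fell. Inherited dystonia genes were not called as a list (2 up and 5 down of 22; adjusted over the list alone 2 and 5; adjusted p = 0.595), and their median of 0.00461 and mean of -0.0829 differed in sign. Within it, Vps16, a vesicle-tethering subunit (-1.03 ± 0.15, adjusted p = 0.00357), and the sarcoglycan gene Sgce (-1.48) fell, and Spr, an enzyme gene of dopamine cofactor synthesis, rose (0.86).

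Genes on the X chromosome stood apart from those of the autosomes. Over 396 X-linked genes with a mean of at least 3 CPM, the median log2 fold change in KO was 0.62, with 0.77 in replicate 1 and 0.47 in replicate 2. The autosomal median over 10782 genes was 0.04. With TMM factors the X-linked median was 0.53. In KO, 155 of the X-linked genes (39.1%) and 848 of the autosomal genes (7.86%) were called up. In C54Y the X-linked median was 0.26, with 0.17 and 0.37 in the replicates, and 16 X-linked genes (4.04%) rose against 92 autosomal genes (0.853%). X-linked genes took 3.18% and 2.50% of reads in WT, 3.50% and 3.30% in C54Y, and 4.73% and 3.52% in KO. Camera over the 20 chromosomes called X up in KO (adjusted p = 3.74e-13) and in C54Y (adjusted p = 5.68e-10), and also called chromosome 2 down in KO (median -0.16, with -0.07 and -0.18 in the replicates, adjusted p = 0.000301) and chromosome 8 up in C54Y (median 0.16, with 0.25 and 0.06 in the replicates, adjusted p = 4.45e-06). No chromosome was called with an estimated correlation (adjusted p = 0.945 with an estimated correlation for X in KO). That test missed a shifted list on simulated data, so it does not decide here either. The chromosome test was chosen after X-linked genes were seen among the leading genes.

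**Figure D3:**
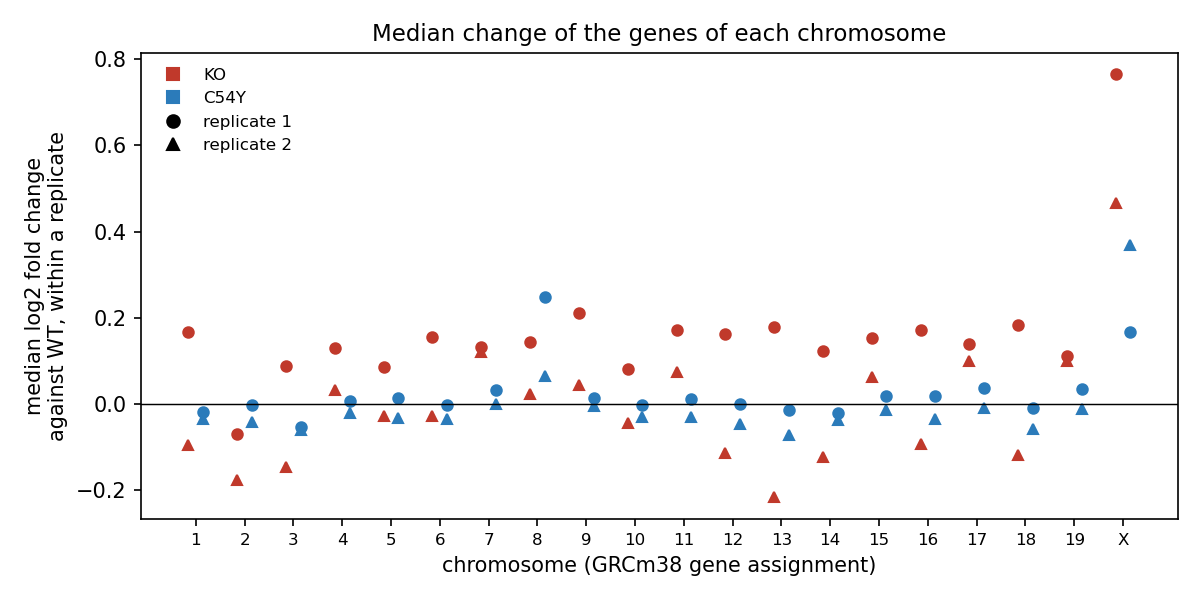
Median log2 fold change against WT of the genes of each chromosome, within replicate 1 (circles) and replicate 2 (triangles), for KO (red) and C54Y (blue). The X chromosome lies at 0.77 and 0.47 in KO, above every autosome.

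The comparison of C54Y with WT asked what a missense change in the DNA-binding domain does on its own. Cuedc2 fell as far as in KO (-3.50 ± 0.17, adjusted p = 0.000106), and the death-domain adaptor gene Cradd (-3.14 ± 0.28, adjusted p = 0.00176), Dph6, which acts in diphthamide synthesis (-2.88 ± 0.26), Fam73a (-2.87 ± 0.26) and Srgn (-2.90 ± 0.30) fell with it. Cd22 (5.43), Xlr3a (4.74 ± 0.37, adjusted p = 0.00125) and the matrix protein gene Mmrn2 (3.66 ± 0.24, adjusted p = 0.000588) rose. Of the naive genes, Zfp42 (2.44 ± 0.18, adjusted p = 0.000877) and Tcl1 (1.61) rose, while Nanog was not called (0.67, adjusted p = 0.117). Prdm14 and Klf2 were also called up, but not without C54Y replicate 2. The core factors Pou5f1 (0.18, adjusted p = 0.551) and Sox2 (0.12, adjusted p = 0.834) were not called. The endoderm genes Cubn (-2.43), Dab2 (-1.79) and Lama1, a basement membrane laminin (-1.30), fell, as did Gusb (-1.98 ± 0.19, adjusted p = 0.00232), and Tuba3a rose (1.97).

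With the block, limma called 208 genes between C54Y and WT, 147 up and 61 down. All had the same sign in both replicates, against 66.1% of all tested genes, which the blocked fit again selects for. In 180 of them the libraries of the 2 groups did not overlap. Without the block limma called 0, with 252 at an unadjusted p under 0.05, and edgeR, limma-voom and DESeq2 called 0, 0 and 22. The blocked count was 69 without C54Y replicate 2, 543 without WT replicate 1, 1818 without KO replicate 1 and 1619 without KO replicate 2. Lists that stayed called with each of the 6 libraries left out were endoderm (0 up and 8 down of 18; adjusted over the list alone 0 and 11; camera adjusted p = 6.7e-14), naive (4 up and 0 down of 19; adjusted over the list alone 12 and 1; adjusted p = 1.65e-10) and two-cell-like genes (2 up and 0 down of 13; adjusted over the list alone 9 and 0; adjusted p = 1.94e-09). The same held for p53 targets (0 up and 0 down of 20; adjusted over the list alone 1 and 5; adjusted p = 0.000122) and imprinted genes (0 up and 3 down of 25; adjusted over the list alone 1 and 9; adjusted p = 0.00219). None held with an estimated correlation (adjusted p = 0.423 with an estimated correlation for all of these). Formative genes were not called in C54Y (1 up and 0 down of 16; adjusted over the list alone 3 and 3; adjusted p = 0.508), nor were fibroblast markers (adjusted p = 0.7).

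Genes changed in both mutants were asked for as the shared response to a missing and an altered THAP1. Cd22, Xlr3a, Xlr5b, Xlr5a and Xlr3b rose most in both, and Cuedc2, Srgn, Cubn, Shld1 and Fam73a fell most. Of the C54Y calls, 144 of the 147 up and 59 of the 61 down were also called in KO, 203 in all, and 0 were called in opposite directions. Independent lists of these sizes would share 13.1 up and 4.52 down. In 100 draws, unchanged groups compared with the same drawn WT libraries shared 0.41 on average and 3 at most. With neither group changed few calls can arise, so the draws do not show what shared WT libraries add beside a changed KO. Without the block limma called 0 genes in both, against 20 by DESeq2, 0 by edgeR and 0 by limma-voom. The blocked overlap was 68 without C54Y replicate 2, 479 without WT replicate 1, 1409 without KO replicate 1 and 1264 without KO replicate 2. Fold changes of KO and C54Y correlated across genes at 0.799, against 0.499 on average in the draws. Between fold changes that share no WT library the correlation across genes was 0.498 (KO replicate 1 with C54Y replicate 2) and 0.589 (KO replicate 2 with C54Y replicate 1). Both WT libraries may come from the same line, and a trait of that line would enter both fold changes. Genes are not independent replicates.

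**Figure D4:**
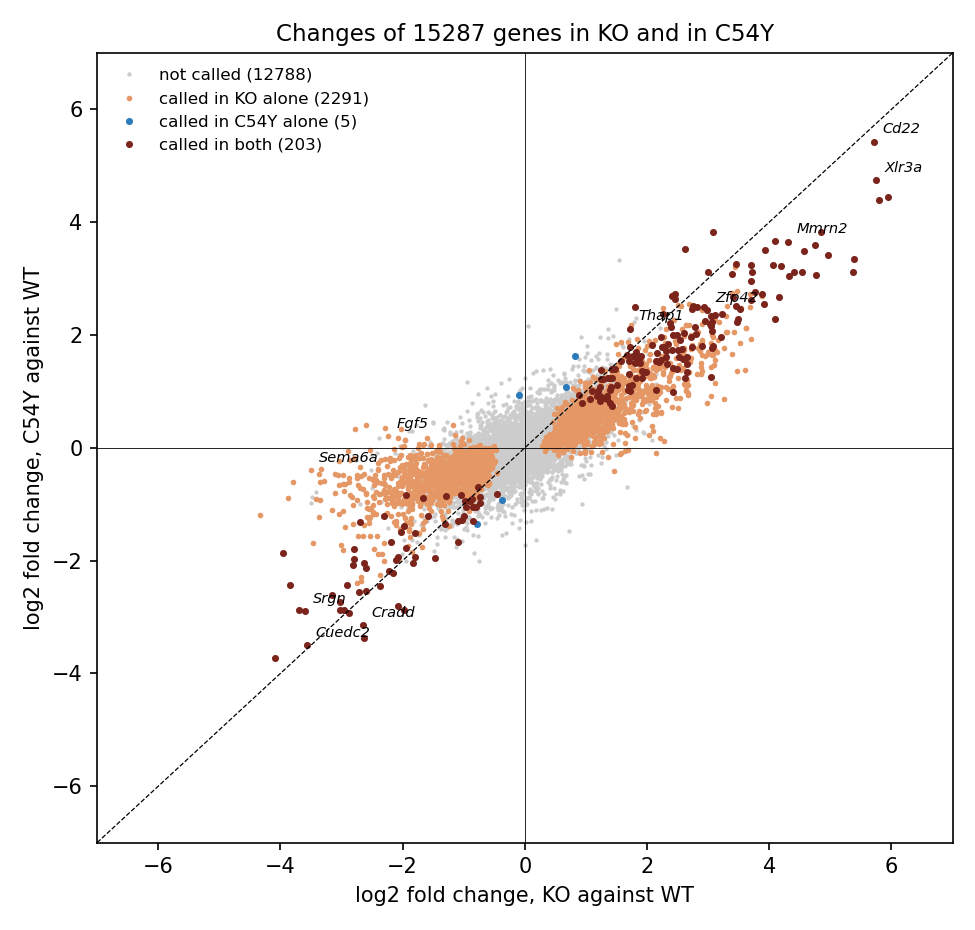
Log2 fold change of 15287 genes in KO (horizontal) and C54Y (vertical) against WT, coloured by which blocked comparison called them; the dashed line marks equal change. The 203 genes called in both all have the same sign, and Sema6a and Fgf5 lie far from 0 in KO alone.

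The direct comparison of KO with C54Y asked where the effects of the mutants differ. Sema6a (-3.10 ± 0.30, adjusted p = 0.0161), the matrix protein gene Spon1 (-2.95), Enpp2, which encodes autotaxin (-2.58), and the imprinted growth regulator Grb10 (-1.77 ± 0.17, adjusted p = 0.0161) were lower in KO. Neither Sema6a nor Grb10 was called between C54Y and WT (Sema6a -0.40, adjusted p = 0.692; Grb10 -0.39, adjusted p = 0.379). Fgf5 (-2.44 ± 0.34, adjusted p = 0.0366), Dnmt3b (-0.98 ± 0.14, adjusted p = 0.0455) and Wnt3 (-2.48, adjusted p = 0.0479) were also lower in KO. The Ras-family gene Mras was higher (1.80 ± 0.20, adjusted p = 0.0161). Without C54Y replicate 1 the calls of Fgf5 (0.0933), Dnmt3b (0.38), Wnt3 (0.126) and Mras (0.0576) were lost. The Dnmt3b and Wnt3 calls were also lost with a filter of 1 CPM or with another pseudocount.

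With the block limma called 29 genes between the mutants, 7 higher and 22 lower in KO. Without it limma called 0, with 207 at an unadjusted p under 0.05, and edgeR, limma-voom and DESeq2 called 0, 0 and 2. The blocked count was 7 without C54Y replicate 1, 80 without C54Y replicate 2, 512 without WT replicate 2, 825 without WT replicate 1, 913 without KO replicate 1 and 2831 without KO replicate 2. Naive genes were called higher in KO than in C54Y (0 called singly; adjusted over the list alone 14 up and 1 down of 19; camera adjusted p = 3.29e-10) and formative genes lower (0 up and 2 down of 16; adjusted over the list alone 2 and 7; adjusted p = 9.4e-06). Oxidative phosphorylation genes were called up (0 up and 0 down of 29; adjusted over the list alone 0 and 0; adjusted p = 2.51e-05). Neuroectoderm genes were called down (0 up and 0 down of 14; adjusted over the list alone 0 and 4; adjusted p = 0.0219). These 4 list calls stayed with each library left out. Endoderm genes were not called between the mutants (adjusted p = 0.226). Two-cell-like (adjusted p = 0.00321), germline (0.00179), core (0.00208), G1/S (0.000526) and fibroblast (9.4e-06) lists were also called, the last down and the others up, and without KO replicate 1 these calls were lost (0.536, 0.605, 0.1, 0.1 and 0.33). The calls of mesoderm genes down (0.00467) and of proteasome subunits (0.000197), ribosomal proteins (0.0219) and replication-dependent histones up (0.0413) were also lost without KO replicate 1 (0.257, 0.442, 0.257 and 0.536). Without C54Y replicate 1 the germline (0.0611), ribosomal (0.137) and histone calls (0.146) were lost, without KO replicate 2 the ribosomal (0.12) and histone calls (0.104), and without C54Y replicate 2 the ribosomal call (0.0898). No member of the two-cell-like, G1/S, fibroblast, proteasome, ribosomal or histone lists was called, singly or adjusted over the list alone. Adjusted over the list alone, germline genes had 4 up, core factors 5 up and mesoderm genes 2 down. None of the 13 lists called between the mutants passed with an estimated correlation (adjusted p = 0.592 with an estimated correlation or higher).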

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

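edgeR with TMM factors had been the planned test and became an alternative once the values were found to be normalized. Tests chosen only after the data were seen were limma with TMM factors, the pseudocounts for single genes, the GC and length correction and the block combined with each other choice; the replicate block on its own, DESeq2 and the library omissions without the block were planned. Without the block, counts of genes stayed at 0 in every comparison under every alternative run except 2: DESeq2 called 184 (KO against WT), 22 (C54Y against WT), 2 (KO against C54Y) and 20 (both mutants), and the replicate block gave 2494, 208, 29 and 203. That limma had 0 calls says little about stability, since it recovered 0 simulated genes without the block. With the block, KO against WT ran from 1749 (without WT replicate 2) to 4861 (without KO replicate 2), and fell to 486 with a minimum fold of 1.5. C54Y against WT ran from 69 (without C54Y replicate 2) to 1818 (without KO replicate 1), with 484 by DESeq2, 52 with the minimum fold, 1743 on the 4 libraries compared and 437 after the GC and length correction. KO against C54Y ran from 7 (without C54Y replicate 1) to 2831 (without KO replicate 2), with 450 by DESeq2, 297 by limma-voom, 0 with the minimum fold (limma; 2349 genes had an unadjusted p under 0.05 without that minimum), 677 on the 4 libraries and 219 after the correction. Genes called in both ran from 68 (without C54Y replicate 2) to 1409 (without KO replicate 1), with 457 by DESeq2, 52 with the minimum fold and 428 after the correction. The minimum fold asks for a larger change by construction; for the others the cause was not tested. Of the 2494, 208 and 29 genes, DESeq2 shared 2248, 207 and 29, and edgeR with TMM factors 2188, 188 and 27. Lists called without the block numbered 11 in each comparison, against 0, 0 and 0 with an estimated correlation and 2, 1 and 0 by fry; the block gave 17 for KO against WT, and a filter of 1 CPM gave 6 for KO against C54Y, which ran from 6 (without KO replicate 1) to 12. With the block 17, 15 and 13 lists were called, 0 in each comparison with an estimated correlation and 0 by fry, and omissions gave 10 (without KO replicate 1) to 20, 8 (without C54Y replicate 1) to 17 and 5 (without KO replicate 1) to 16. Of 329 named results, 150 were called with the block and 0 without it, and none reversed. The minimum fold lost 78 of the 150, DESeq2 7, and omissions from 2 (KO replicate 2) to 28 (WT replicate 2). Depth limits the genes with few WT reads, such as Xlr5b and Dux, whose folds are imprecise.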

Other observations

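Tests chosen only after their results were seen were the comparison with feeder markers, split by genotype once its combined result was known, the replicate test of X-linked dose and the removal of multicopy X-linked families. Signalling genes outside the lists described above also moved in KO. Dusp6, a phosphatase gene induced by ERK, fell by 1.53 on the log2 scale in KO (-1.53 ± 0.16, limma with the block, Benjamini-Hochberg adjusted p = 0.000945), and FGF and ERK targets were called down (0 up and 3 down of 16; adjusted over the list alone 0 and 3; camera adjusted p = 0.0199, and adjusted p = 0.553 with an estimated correlation), a call lost without KO replicate 1 (0.129). Lefty2, a Nodal antagonist gene, rose by 1.75 ± 0.15 and Skil, a brake on the same pathway, fell by 0.98 on the log2 scale (-0.98), so Nodal and BMP targets went both ways (3 up and 4 down of 14; adjusted over the list alone 4 and 4; adjusted p = 0.735). The cyclin gene Ccnd3 rose by 1.35 ± 0.14 (adjusted p = 0.000788), within a list of D cyclins and kinase inhibitors that was not called (4 up and 3 down of 12; adjusted over the list alone 4 and 3; adjusted p = 0.846). Xbp1, a regulator of the secretory pathway, rose by 1.12 ± 0.15, and endoplasmic reticulum chaperones narrowly missed the threshold (3 up and 0 down of 17; adjusted over the list alone 3 and 0; adjusted p = 0.0504). The X-linked trophectoderm genes Rhox9 (2.08) and Rhox6 (1.90) rose. Tfap2c was also called up and Cdx2 down, calls lost without WT replicate 2 and without KO replicate 1, in that order. The trophectoderm list was not called and its test pointed up against a mean of -0.249 (5 up and 2 down of 17; adjusted over the list alone 6 and 4; adjusted p = 0.762).

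Ribosomal proteins were called up in KO (3 up and 0 down of 38; adjusted over the list alone 1 and 0; adjusted p = 0.0351, and adjusted p = 0.49 with an estimated correlation), a call lost without any 1 of the 6 libraries, for example WT replicate 2 (0.0977) or KO replicate 1 (0.226), with 0.15 (WT replicate 1), 0.118 (C54Y replicate 1), 0.15 (C54Y replicate 2) and 0.125 (KO replicate 2), and also with TMM factors (0.283). Lists not called in KO were apoptosis regulators (adjusted p = 0.344), mitosis (0.278), double-strand break repair (0.409), ATF4 targets (0.344), cholesterol synthesis (0.846), proteasome (0.622), replication-dependent histones (0.0768), Hox genes (0.126), interferon-stimulated genes (0.799) and the THAP family (0.522). In C54Y further lists passed in the preset test and none with an estimated correlation (adjusted p = 0.423 with an estimated correlation or higher). Proteasome subunits were called down (adjusted p = 0.00189), a call lost without C54Y replicate 1 (0.218) or WT replicate 2 (0.263), and ATF4 targets down (0.00211), lost without C54Y replicate 1 (0.093) or WT replicate 1 (0.0531). Germline genes up (0.0057), FGF and ERK targets down (0.0057) and Wnt targets down (0.0199) were lost without C54Y replicate 2 (0.223, 0.143 and 0.133), and germline and Wnt calls also without WT replicate 1 (0.116 and 0.0814). Lysosome genes down (0.00923), G1/S genes up (0.0257), Hox genes down (0.0341), mesoderm genes down (0.0446) and glycolysis genes up (0.0196) were lost without WT replicate 1 (0.844, 0.844, 0.496, 0.547 and 0.0531) or C54Y replicate 1 (0.093, 0.243, 0.194, 0.0916 and 0.0693). Other omissions also ended the calls of G1/S (C54Y replicate 2, 0.0748), Hox (KO replicate 1, 0.0884; KO replicate 2, 0.104), mesoderm (C54Y replicate 2, 0.0919; KO replicate 1, 0.0799; KO replicate 2, 0.0774) and glycolysis genes (C54Y replicate 2, 0.0919; WT replicate 2, 0.0719). No member of the ATF4, Wnt, G1/S, Hox or mesoderm lists was called in C54Y, singly or adjusted over the list alone. Of the proteasome list Psmb5 alone was called. Members called singly were 1 up of 18 germline, 2 down of 28 lysosome and 1 up of 23 glycolysis genes. FGF and ERK targets had 0 called singly and 4 down adjusted over the list alone.

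Sex-chromosome transcripts were measured as a check of the lines. Xist had 117, 410 and 341 normalized counts in WT, C54Y and KO of replicate 1 and 12.9, 18.2 and 17.8 in replicate 2, and it was not called (adjusted p = 0.118 in KO and 0.245 in C54Y). Tsix ranged from 17.8 to 64.3. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 10.4 normalized counts in any library. No genotype thus showed clear Y-linked expression. The labels give neither the sex nor the karyotype of the lines, and these counts do not tell how many X chromosomes they carried.

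The gain of naive and loss of endoderm transcripts may reflect fewer differentiating cells, and fewer feeder cells were weighed against it. In C54Y the endoderm median minus the fibroblast median was -1.05 and -1.33 in the replicates, which argues against feeder loss as its cause there. In KO it was -0.21 in replicate 1, where Col1a1 had 554 normalized counts against 1500 in WT, and -1.17 in replicate 2, so in KO replicate 1 the endoderm change and feeder loss cannot be told apart. GC content and length did not account for the KO change, since the endoderm median was -0.830 before the correction and -0.903 after it. After it 10 of 10 endoderm genes stayed called, which says little, because the corrected fit called 3632 genes against 2494. Whether the X-linked dose drives these genes stays open as well: the KO replicate with the larger X-linked median differed from the other by 0.206 (SE 0.183) for endoderm and 0.173 (SE 0.127) for naive genes, and that of C54Y by 0.165 (SE 0.127) and 0.161 (SE 0.107). Each SE was taken over the members of a list (18 endoderm, 19 naive) within a single pair of libraries. It does not measure the spread between cultures, so this test cannot decide the question. All 4 differences were positive and within 2 SE, a sign that goes against the dose for endoderm and with it for naive genes. Earlier forms of this test, pairing libraries (1 of 4 pairs for endoderm and 4 of 4 for naive) or asking for 1 SE, would have counted against it for endoderm and for it in naive genes. The limit of 2 SE was set after those outcomes were seen.

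A higher dose of the X chromosome in KO is a candidate explanation for the X-linked rise there, and it stays open. Of 177 X-linked genes with at least 30 CPM, 91.0% and 87.6% lay above the autosomal median in the KO replicates and 78.5% and 90.4% in those of C54Y. These shares show that the rise was broad in both mutants; they describe the same shift as the raised median and do not tell dose from another chromosome-wide cause. Reads shared within multicopy families do not account for the rise in KO, because without them the lower replicate median was still 0.431, and GC content and length do not, because X exceeded the autosomes by 0.573 after correction. A difference in X chromosome number or activity between the lines, which the genotype could cause or which could have arisen in culture, stays open, since each genotype may come from 1 line. The changes of naive, germline and imprinted genes and of Dnmt3b were not measured apart from it.

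The C54Y protein may act as a partial loss of function, although Cuedc2 and Gusb fell alike in both mutants (KO against C54Y -0.07 and -0.13), and Shld1 and Psmb5 fell further in C54Y, which a partial loss does not predict (KO against C54Y 0.74 and 0.37, neither difference called, adjusted p = 0.286 and 0.24). For autosomal genes chosen for over 2-fold change in KO in replicate 1 (1186 genes), the C54Y change in replicate 2 was 54.9% of that of KO, and with the replicates exchanged (843 genes) it was 40.0%. The genes lowest in C54Y, when chosen in replicate 2, changed in KO by 190% of the C54Y change in replicate 1, and with the replicates exchanged by 134%. KO changed more both ways round, and 31.4% and 30.3% of these genes fell further in C54Y. The 134% stayed short of the limit set in advance against equal loss, so whether these genes are lost as fully in both mutants stayed open. Shared WT libraries within a replicate and a difference between the lines in X-linked dose were not removed from these shares.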
